A study of Bos taurus with 12 samples.

How the data were processed

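RNA was prepared from the fat layer of milk from 6 Holstein cows in early lactation, and each cow contributed 1 control library and 1 library with postruminal lysine, giving 12 libraries. Per the labels' protocols, milk was centrifuged, the fat was taken off and extracted with Trizol and chloroform, the total RNA was cleaned on a column, and libraries were made by standard Illumina methods. The deposited table holds whole-number read counts per gene, 1 column per library and 24616 rows, each named by an Ensembl cattle gene ID; these counts were not normalized and no libraries were pooled, as the file's values and header show. The aligner, the counting tool, its strand setting, the genome build and the annotation release are not given in the sources used here. All 12 columns carry the exact description of 1 sample, and no column belonged to another sample. No row lacked a gene ID, 8083 rows were 0 in every library, and no 2 libraries were identical.

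The IDs could not be turned into gene names: the table of 37063 RefSeq genes used here pairs none of the 24616 IDs with a symbol (0 matched). The lists of milk synthesis, amino acid, signalling, translation, energy, stress, immune and growth genes and of cell type markers that had been fixed before the data were examined, as were the named-gene rule and the main design, were therefore not tested. Genes are described by rank of abundance or by ID, at most 2 IDs in each direction, and no gene positions are given.

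Groups and cow numbers were taken from the sample titles. The label of the lysine libraries gives the treatment as 63 days; titles and descriptions carry only the codes 0 and 63, and the labels do not settle whether the 63 in them is a duration or an amount. The descriptions also carry a code B (1 or 2, fixed within a cow) and a code P (1 to 4, different for the 2 libraries of a cow), whose meaning the labels do not give. In 4 cows the P code of the lysine library was 1 lower than that of the control, and in cows 4394 and 4408 it was 3 higher. The 2 libraries of a cow come from the same animal, so cow was a block in the main design. Deviations from the group means correlated between the libraries of a cow at -0.02 to 0.66 (median 0.19, across genes), against a median of -0.03 between libraries of different cows, and 3 of the 6 control libraries correlated best with their own cow.

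Counts were tested with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr (a minimum count of 10, about 0.48 CPM, counts scaled to a common library total, at the median total, in at least 6 libraries), which left 11323 genes holding 99.9% of all counts. TMM factors ranged from 0.44 to 1.41. Robust quasi-likelihood models with cow and treatment were fitted and tested two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Interaction terms tested whether the lysine effect differed between the B codes or between the 2 orders of the P codes, and an F test of the cow coefficients tested differences between cows. Standard errors were taken as the log2 fold change over the square root of F, and 95% intervals from them; they are not adjusted for the number of genes. Values per library (total, genes detected, share of the 10 most abundant genes, and 4 measures of library complexity added after the data were seen) were compared by exact two-sided sign-flip permutation over the 6 cows, which cannot give a p below 0.0313. Genes detected at a common depth are the number expected in a draw of 5.45 M counts. The expected count of a gene in a library is the mean of its normalised level in the other 11 libraries times that library's effective total; log2 ratios of observed to expected counts used an offset of 0.5. Variance shares, correlations and principal components used log2 CPM with a prior count of 2. The chance medians of the variance shares are those of beta distributions for independent normal values.

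Totals ranged from 5.45 to 56.6 M counts per library (median 20.8 M; M is the metric prefix mega), a range of 10.4 times. Reads without molecular identifiers are not independent molecules, so depth gives counting error only. In simulated data with the fitted means, library sizes and spread of these 12 libraries, 200 of 11323 genes were changed (5 runs). The within-cow test of lysine against control called 1.6% of 1.5-fold, 22.4% of 2-fold, 62.4% of 4-fold and 82.4% of 8-fold changes, with a mean of 5.0 false calls. Genes were drawn independently, with 1 spread per gene for all libraries. Of the unchanged simulated genes 4.27% had an unadjusted p under 0.05, against 2.53% of the tested genes in the real data. The simulated test was thus less conservative than the real one, and these shares may be too high.

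The named genes follow a fixed rule: as fewer than 10 genes passed, the genes of each direction with the smallest p among those at a mean of 5 CPM or more, here the first 2 of each 10. The rule also named milk protein, fatty acid and amino acid genes by symbol, which could not be looked up. Alternatives were the fit without the cow block, DESeq2 1.42.0, limma 3.58.1 (voom, also with cow as a random block), DESeq2-type size factors, scaling without the 20 most abundant genes, no filter and a stricter filter (5 CPM in 6 libraries), the P or B code as a covariate, and each cow left out in turn. Library totals as the only scaling, the log2 library total as a covariate and the removal of cows 4394 and 4408 together were added after the data were seen.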

Results

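The transcriptome of the milk fat layer was profiled by RNA sequencing in 6 early-lactation Holstein cows, each sampled as a control and with lysine supplied beyond the rumen. Lysine is an essential amino acid, and postruminal supply delivers it past the rumen microbes. Milk fat globules carry small amounts of cytoplasm of mammary secretory cells, so their RNA serves as a sample of the gland without biopsy. There were 6 control and 6 lysine libraries, 1 of each per cow. Control libraries held 17.6 ± 8.80 M counts and lysine libraries 28.4 ± 17.6 M (mean ± SD, n = 6 each). The lysine library was the deeper of the 2 in 5 of 6 cows, by 10.7 ± 22.8 M counts on average over the 6. This within-cow difference was not past the threshold (exact sign-flip permutation p = 0.313, adjusted p = 0.906 over 7 measures). The mean difference was 4.07 M without cow 4381 and 18.0 M without cow 4319.

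Milk fat RNA was dominated by a handful of genes in every library. The 8 most abundant genes, ranked by their mean share over all 12 libraries, took 68.7 ± 8.29% of all counts (mean ± SD, n = 12), and the 10 most abundant genes within a library took between 60.4% and 86.8%. The most abundant gene held a steady share, 20.3 ± 2.40% in control and 19.2 ± 3.86% in lysine libraries (n = 6 each). The second most abundant gene ranged far more widely, from 3.65% in the lysine library of cow 4394 to 45.8% in the lysine library of cow 4383. The third to eighth genes held mean shares of 10.4%, 8.92%, 5.77%, 4.01%, 2.97% and 1.05% in control libraries and 8.53%, 6.60%, 5.58%, 3.42%, 2.39% and 0.94% in lysine libraries. Between 10687 and 15319 genes had at least 1 count in a library.

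The share of the 10 most abundant genes showed no within-cow difference past the threshold. It was 68.6 ± 5.94% in control and 71.8 ± 10.5% in lysine libraries, was higher with lysine in 4 of 6 cows, and gave an exact sign-flip permutation p of 0.531. Genes detected numbered 12938 ± 1601 in control and 13090 ± 786 in lysine libraries (higher with lysine in 3 of 6 cows, exact sign-flip permutation p = 0.813). At a common depth of 5.45 M counts, 12275 ± 1102 and 12305 ± 421 genes were expected (exact sign-flip permutation p = 0.906). Adjusted p was 0.906 for each of these measures. The sign of the mean difference hung on single cows: the share of the 10 most abundant genes differed by -0.236 percentage points without cow 4383, genes detected by -193 without cow 4383, -121 without cow 4394 and -13.6 without cow 4408, and genes at common depth by -223 without cow 4394 and -112 without cow 4408.

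**Figure D1:**
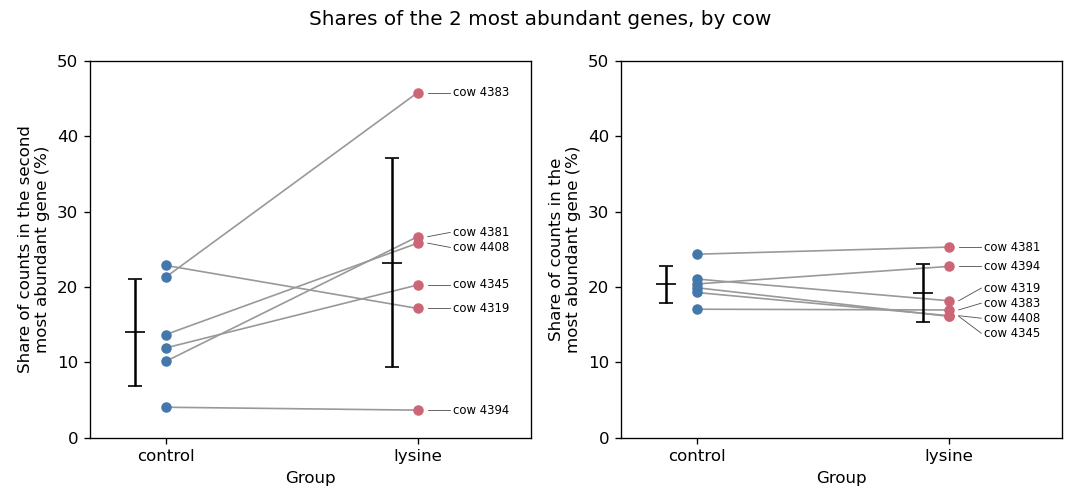
Share of all counts (%) held by the second most abundant gene (left) and the most abundant gene (right) in the control and lysine library of each of the 6 cows; grey lines join the libraries of a cow, thin lines lead from its lysine point to its number, and black bars are group means ± SD. The second most abundant gene spans 3.65% to 45.8% and the most abundant gene stays near its means of 20.3% and 19.2%.

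The main comparison asked whether postruminal lysine changed the mammary transcriptome, with each cow as its own control. No gene passed the threshold: of 11323 genes tested, 0 were higher and 0 lower with lysine at an adjusted p under 0.05 (edgeR quasi-likelihood test with cow as a block, Benjamini-Hochberg), and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 286 genes, 159 higher and 127 lower, or 2.53% of those tested against a nominal 5%. The 32 ways to split the libraries within all 6 cows, the real one included, gave a median of 305.5 such genes. The other splits ranged from 96 to 1189, so 286 was not unusually few. DESeq2, limma voom and voom with cow as a random block also called 0 genes, with 543, 584 and 589 genes at an unadjusted p under 0.05. All 6 cows moved the same way for 345 genes (178 higher, 167 lower), where independent coin flips would give 354.

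The abundant genes that make up most of the milk fat RNA showed no change past the threshold. After normalisation the log2 fold change of the most abundant gene was 0.20 ± 0.33 (SE, 6 cows), and the third to eighth genes lay between -0.20 and 0.25. The second most abundant gene had a log2 fold change of 0.91 ± 0.43 (95% interval -0.03 to 1.85, higher in 5 of 6 cows after normalisation, unadjusted p = 0.057 and adjusted p = 1 by edgeR). Its share of counts was 14.0 ± 7.08% in control and 23.2 ± 13.8% in lysine libraries (n = 6 each), and was larger with lysine in 4 of 6 cows. The ninth most abundant gene had a log2 fold change of 1.03 ± 0.49 (95% interval -0.03 to 2.09, higher in 4 of 6 cows). With library totals as the only scaling the median log2 fold change of all genes moved from 0.04 to -0.26, and that of the second most abundant gene became 0.61. The log2 fold change of the second most abundant gene was 0.58 without cow 4383 and 1.37 without the cow block.

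Among genes at 5 CPM or more, the 2 of each direction with the smallest unadjusted p differed in that direction in 5 or 6 of the 6 cows, and none passed the adjusted threshold. That agreement between cows follows in part from picking these genes by p. ENSBTAG00000007303 measured 126 ± 40.1 normalised CPM in control and 342 ± 272 in lysine libraries (n = 6 each), a log2 fold change of 1.12 ± 0.31 (SE) and higher with lysine in 6 of 6 cows. ENSBTAG00000001181 measured 13.1 ± 8.06 and 23.9 ± 17.6 CPM, a log2 fold change of 0.81 ± 0.23, higher in 5 of 6 cows. ENSBTAG00000018828 measured 12.7 ± 4.59 in control and 6.0 ± 2.53 in lysine libraries, a log2 fold change of -1.14 ± 0.28, lower in 6 of 6 cows. ENSBTAG00000010658 measured 63.8 ± 11.7 and 41.8 ± 5.17, a log2 fold change of -0.60 ± 0.17, lower in 6 of 6 cows. Their unadjusted p values by edgeR were 0.0035, 0.0046, 0.0016 and 0.0035, and the adjusted p of each was 1.

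**Figure D2:**
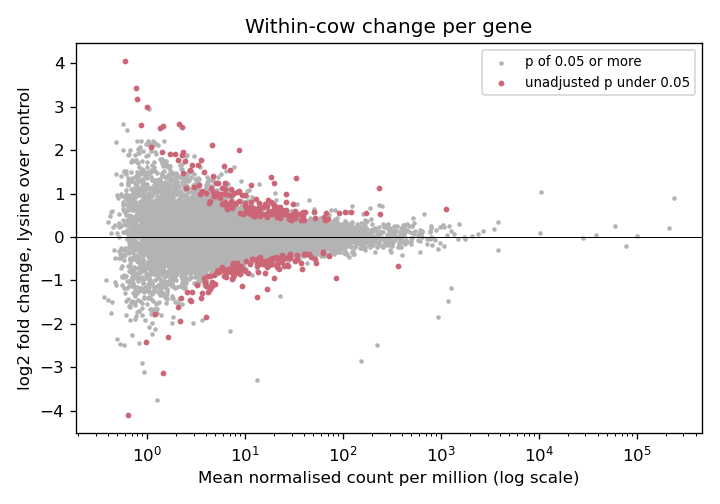
Log2 fold change of lysine over control, fitted within cows, for each of 11323 genes (points) against its mean normalised CPM (log scale); coloured points have an unadjusted p under 0.05. The 286 coloured genes lie on both sides of 0, 159 above and 127 below, and none passed an adjusted p of 0.05.

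The precision of these data bounds the size of change in genes at 5 CPM or more. For the 7358 genes at a mean of 5 CPM or more, the median half-width of the 95% interval was 0.58 on the log2 scale, or 1.49-fold. The interval lay within a 2-fold change for 5497 of these genes (74.7%) and within a 4-fold change for 7242 (98.4%). Over all 11323 tested genes, scarcer ones included, detection was only partial: simulated 2-fold changes were called in 22.4% of cases and 4-fold changes in 62.4%. Both shares may be too high, as the simulated test was less conservative than the real one. The number of genes at an unadjusted p under 0.05 was 142 without cow 4345, 171 without cow 4381, 458 without cow 4383 and 635 without cow 4394, with 0 genes past the adjusted threshold each time.

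The cows were also compared with each other. A test of the cow terms called 161 of 11323 genes (edgeR quasi-likelihood F test, adjusted p under 0.05), where the test of lysine called 0; the sizes of the 2 effects were not tested against each other. Cow 4345 was the farthest from the median cow for 64 of them, 57 higher, and cow 4394 for 76, 65 of them lower. Of those 65 genes, 28 had no count in the control library of cow 4394, 17 had none in its lysine library and 16 had none in either. In the control library 8.73% of the genes with an expected count of 20 or more were at 0, and in the lysine library 2.76%. Over all tested genes cow took a median of 55.5% of the variance of log2 expression and treatment 3.63%, where chance alone gives medians of 44.9% and 4.67%. The cow count depended on single cows, at 92 genes without cow 4319, 9 without cow 4345, 72 without cow 4381 and 429 without cow 4408. Without cow 4394 it was 140 genes, but only 73 of them were among the 161. The count also depended on the setting. It was 18 with the log2 library total as a covariate, 396 with library totals as the only scaling, 829 without a low-count filter and 1518 with DESeq2.

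**Figure D3:**
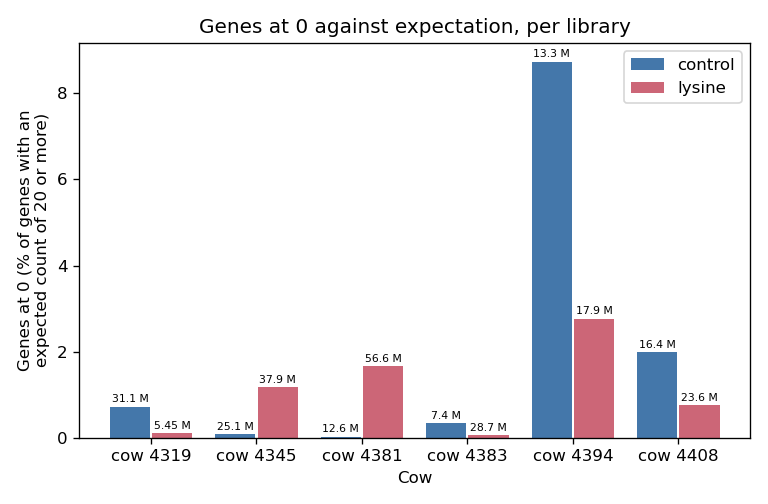
Genes with a count of 0 as a percentage of the genes with an expected count of 20 or more, per cow, for control and lysine libraries; numbers above the bars are library totals (M counts). The control library of cow 4394 reaches 8.73%, and the other 11 libraries lie between 0.020% and 2.76%.

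The lysine effect was also compared between the cows coded B1 and B2 (3 each) and between the 2 orders of the P codes. No gene differed between the B codes at an adjusted p under 0.05 (edgeR interaction test, smallest adjusted p = 0.684), with 784 genes at an unadjusted p under 0.05. That number was 1219 without cow 4319, 329 without cow 4345 and 503 without cow 4408, and 1 gene was called without cow 4394. No gene differed between the 4 cows with the lower and the 2 cows with the higher P code in the lysine library (edgeR, smallest adjusted p = 0.232), with 796 at an unadjusted p under 0.05, or 467 without cow 4345, 495 without cow 4381 and 2861 without cow 4408. These edgeR tests had little power. In simulated data (2 runs each) the B code test called 1% of 2-fold, 15% of 4-fold and 57% of 8-fold differences in the lysine effect. The P code test called 0%, 11% and 40%, so most 2-fold and 4-fold differences would be missed. DESeq2 called 39 and 114 genes in the B and P comparisons. Leaving out cow 4394 or cow 4408 leaves 1 cow in the second group; the P comparison then called 87 and 847 genes, which sets 1 cow against 4 and assumes that it varies like the others. Within cows, a linear term for the P code and this comparison span the same differences and cannot be told apart.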

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

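The tests of sequencing depth, of a cell mix in both libraries of a cow and of 4-fold bounds were chosen after the results were seen, as were the complexity measures. The fit without cow 4394 was planned, but its reading as a test of added spread was chosen afterwards. The tests of summed counts, spread and splits were written down first. The prediction on a cell mix in 1 sample named all other libraries, and its comparison with the 10 libraries of the other cows was set later. In 32 groups of 6 libraries, 4 values stood apart by Dixon's test at the 95% level, which chance gives in about 1 group in 20.

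The control library of cow 4394 held 0 counts for 8.73% of the genes with an expected count of 20 or more, against 1.99% in the next control library. Sequencing depth is argued against, since at a common depth of 5.45 M counts this library would hold 10493 genes and the lowest of the others 11791 (SD of the others 587). A plain loss of genes in that sample is not decided. Summed over genes expected at 20 to 100 counts, observed over expected counts was 1.02, within the 0.88 to 1.57 of the others. That range is wide against 8.73% of genes at 0, so the sum could stay within it despite such a loss. An exchange of one set of genes for another stays open too. Another mix of cells in that sample alone is not decided. It predicted an SD of the log2 ratio above that of the other cows for genes expected at 1000 to 10000 counts. That SD was 0.72, within the 0.48 to 0.88 of their 10 libraries, so the prediction was not met there. For genes expected at 100 to 1000 counts, however, the SD was 1.47, the highest of all 12 libraries. A mix in both libraries of cow 4394 stays open. Its lysine library was at 1.0 for genes expected at 1000 to 10000 counts, the highest of all 12. That lysine library also had the second highest share at 0 (2.76%). Also open, as a hypothesis, is that the control library of cow 4394 came from few starting molecules. That may give its spread of 2.94 at 20 to 100 expected counts, above the highest of the others (2.17). Genes at 0 widen that spread, so it restates the observation in part and is no separate support. The design gives no biological explanation for a single library.

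No gene was called between lysine and control, and of the 32 splits that part all 6 cows, 18 gave at least the 286 genes at an unadjusted p under 0.05 of the real split, so chance cannot be excluded (highest other 1189). The split by library depth gave 347 genes, the split by P code 388 and the split by genes detected at common depth 503, each with 0 called; 68 drawn from the 420 splits that part 2 or 4 cows, some of which amount to the same test, gave 16 to 1434 such genes. Of these, 4 called any gene (up to 65), as did 1 of the 32 (4 genes). Argued against are 4-fold changes in many well-expressed genes, since 98.4% of the intervals of genes at 5 CPM or more excluded them. The spread added by the control library of cow 4394 stays open: without that cow 0 genes were called, but 635 were at an unadjusted p under 0.05, and so do smaller changes and changes in scarcer genes, as the simulated 4-fold changes were called in 62.4% of cases over all tested genes.

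Between the B codes, 1 of the 10 splits of the cows into 3 and 3 gave as many genes at an unadjusted p under 0.05, the real one with 784 (highest other 740); 10 splits are too few for a share under 0.05. The lysine library of cow 4383 had 1048 genes with exactly 1 count, against 411 in the next lysine library, and the controls of cows 4345 and 4381 had 1005 and 1117. The lysine library of cow 4345 had observed over expected counts of 1.57 for genes expected at 20 to 100 counts. The next lysine library was at 1.10, and the control of cow 4345, the highest control, was at 1.36. For ENSBTAG00000001181 the lysine library of cow 4345 stood at 57.9 normalised CPM, against 26.7 in the next lysine library. The control of cow 4345, at 28.2, was the highest control. Without that cow the log2 fold change of this gene was 0.77.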

How the results depend on the processing

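The count of 0 genes for lysine held in 18 of 19 alternatives, among them no replicate block (0 genes, 202 at an unadjusted p under 0.05 against 286 with cow as the block); blocking changed no call. Without a low-count filter 1 gene was called, with 2313 counts in the control of cow 4381 and at most 1 elsewhere. The 4 named genes and the second most abundant gene kept their direction in all 19 alternatives and passed the threshold in none. The 4 named genes were picked from these same libraries by p, so their kept direction is no separate support. The comparison of B codes gave 39 genes with DESeq2, 30 without a filter and 0 to 1 with a cow left out; that of P code orders gave 114, 48 and 0 to 847. The cow effect was 161 genes, 1518 with DESeq2 (all 161 among them), 829 without a filter, 9 to 429 with a cow left out, 396 with library totals as the only scaling and 18 with the log2 library total as a covariate; the cause was not tested. Leaving out a cow moved mean differences (lysine minus control), none past the threshold, over -193 to 480 for genes detected, -223 to 240 for genes at common depth, -0.24 to 5.58 percentage points for the share of the 10 most abundant genes, -273 to 47.8 for genes with 1 count, -23.1 to 1.72 for the effective number of genes (exponential of the Shannon entropy) and -1.40 to 0.125 percentage points for genes at 0; with 5 cows the exact p cannot fall below 0.0625. Gene list tests and marker means could not be run, since no ID had a name. Depth and spread limit what can be seen: 22.4% of simulated 2-fold changes were called.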

Other observations

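All tests in this part were chosen after the data were seen. The second most abundant gene, whose share of counts ran from 3.65% to 45.8%, may follow library depth within cows. Over the 6 cows, the log2 change of its share correlated with the log2 change of the library total (Pearson r = 0.86, exact permutation p = 0.0028; Spearman rho = 0.94, exact permutation p = 0.017; adjusted p 0.0056 and 0.033 over 2 relations). The share of the most abundant gene showed no such relation past the threshold (Pearson r = 0.44, exact permutation p = 0.436; Spearman rho = 0.09, exact permutation p = 0.919), so the relation was not seen for the other gene of like abundance. Without cows 4319 and 4381, the farthest in depth, r over the other 4 cows was 0.60 (exact permutation p = 0.333), so the test rests on those cows. Lysine stays open as an explanation: the fold change of this gene was 0.91 on the log2 scale, 0.55 with the log2 library total as a covariate, and lysine libraries were the deeper in 5 of 6 cows.

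Of the first 2 principal components of log2 expression (35.2% and 19.2% of the variance), the first had the control of cow 4394 at 152 and the other 11 libraries between -76.1 and 59.0, the highest of them the lysine library of that cow. The controls of cows 4394 and 4408, which share the code P1, lay at opposite ends of the second component (85.1 and -65.4).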
